A study of Mus musculus with 2 samples.

How the data were processed

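Single-cell RNA was measured by Drop-seq in 1 MI library (1 heart) and 1 sham library (4 hearts pooled), with 12 PCR cycles in the Nextera XT step, per the labels' protocols. The labels describe fixation in paraformaldehyde and embedding; how cells were brought into suspension is not given in the sources used here. They also give an exclusion of mice by a pressure gradient over an aortic constriction, whose place in a coronary ligation experiment is not explained there. The deposited values are raw UMI counts per gene and cell barcode, in 1 table per library. The submitters' processing notes name the genome build mm10 and the tool Seurat, with no version or role; the aligner, the counting program and the gene annotation are not given in the sources used here. Every barcode in both tables had at least 500 genes with a UMI, a limit that no label states, so the tables had been filtered before deposit. The barcodes ending in N, 317 in MI and 671 in sham, were kept as deposited. The MI data listed 24139 genes and the sham data 23970, of which 21745 were in both and entered the comparisons. A gene listed in only 1 table was not compared. The male label was checked on Xist, with 3 and 4 UMIs, and Ddx3y, with 2907 and 1341 UMIs in the MI and sham libraries.

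Cells with at least 200 genes and at most 25% of UMIs from mitochondrially encoded genes were kept, which removed 114 MI and 34 sham barcodes. Doublets were called with scrublet in scanpy 1.11.5 in each library and removed, 154 in MI (1.82%) and 359 in sham (5.70%). Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 20 neighbours entered a shared-neighbour graph that was clustered with leidenalg 0.10.2 at resolution 0.8, both libraries together and without integration. The other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

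Clusters were named from 18 marker lists fixed before the data were examined. How markers were scored, and the joining of macrophage with monocyte, T cell with NK cell and pericyte with smooth muscle markers, were decided after the clusters were seen. Only classes with at least 3 markers detected in at least 10% of the cells of some cluster could be taken. Of these, a cluster took the class with the highest mean marker level relative to the highest cluster. It stayed unnamed with under 3 markers of that class detected in at least 10% of its cells. The same held with more markers of another class than of its own among its 10 leading genes. Nearly every large cluster came from 1 library, so a class joins different clusters of each library. Genes that lead such a cluster then also stand out in the comparison of the libraries, and the cell classes can differ from those of the study.

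With 1 library per group no test between conditions was possible, and no p-value was computed. Shares of kept cells have exact Clopper-Pearson 95% intervals. For each class with at least 50 kept cells in each library, UMIs were summed over its cells and given as CPM of the class total with exact Poisson 95% intervals. The log2 ratio of MI over sham has an exact conditional binomial 95% interval. All of these cover counting error only. A gene with 0 UMIs in a class of 1 library was set to 3 counts over the class there, which makes its ratio a bound. For each of 29 gene lists fixed before the data were examined, the median log2 ratio was taken over members with at least 20 UMIs in the class. Its interval comes from 1000 Poisson draws, and its percentile from 10000 random lists of the same size matched on mean expression in 20 bins. Counts of members at least 2-fold higher or lower are counts by size.

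Named genes followed a rule fixed beforehand. In each class, genes with at least 50 UMIs and a UMI in at least 5% of cells in 1 library were ranked by the bound of the interval of the CPM ratio that lies nearest to 1. The 12 highest above and the 12 lowest below 1 were named, with 3 members per list of largest bound. Mitochondrial, ribosomal protein, hemoglobin, Y-linked, Xist and Gm or Rik genes were left out. Coordinates are those of GENCODE vM21 on GRCm38, which is mm10. For shares of cells with a UMI, each cell was thinned to 500 UMIs, which left out no cell, and T/NK-like and B cell-like cells served as the background of free RNA.

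The ratio and list steps were tested on simulated data with 200 genes changed 2-fold or 4-fold. Both simulated libraries were Poisson draws around 1 shared profile, without variation between libraries, animals or cells. Coverage near 95% thus followed from the design, and the simulations cover counting error only. In the fibroblast-like simulation over 11748 genes, 95.9% of intervals of unchanged genes held the true value and the interval excluded 0 for 93% of 2-fold and 100% of 4-fold changes. The macrophage/monocyte-like simulation over 9842 genes gave 96.2%, 91% and 100%, and the endothelial-like one over 9551 genes 95.6%, 96% and 100%. Lists of 12 unchanged genes fell outside the middle 95% of random lists in 3.75%, 7.50% and 4.75% of 400 draws in these 3 simulations, and a list of 12 genes raised 4-fold lay at percentile 100 in each. The number of draws was raised from 20 after 1, 6 and 3 of the first lists were seen to lie outside. Alternatives fixed beforehand were a 500-gene minimum, a mitochondrial limit of 10% or none, doublets kept, Leiden resolutions 0.4 and 1.5, each library clustered on its own, median-of-ratios scaling, CPM without the 50 most abundant genes, the mean over cells of counts per 10000, and list members with at least 100 UMIs or with 1 UMI in each library. Chosen after seeing the data were the best marker class for unnamed clusters, leaving out cycling clusters, leaving out clusters 13 and 16 of the endothelial-like class, thinning before summing, and subtracting free RNA as the library's mean profile at 14.2% of MI and 14.2% of sham UMIs, the level of 3 collagen genes in lymphocytes relative to the whole library. A second level, 7.60% in MI and 4.81% in sham, came from the number of lymphocytes with a UMI of these genes, which a few cells rich in collagen cannot raise. Giving no ratio where both libraries are left at or under 3 counts was added to the subtraction after its first values were seen.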

Results

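Drop-seq, a droplet method that tags each mRNA molecule with a cell barcode and a unique molecular identifier (UMI), was applied to hearts of male C57BL6/J mice aged 8 to 10 weeks. Cells were profiled 14 days after ligation of the left anterior descending coronary artery (MI) or after sham surgery. The MI library came from 1 heart and the sham library from 4 pooled hearts, so each group was 1 library and no difference had a replicate check. The series set out to identify the cell populations of the injured heart. The MI data held 8555 barcodes and 33275336 UMIs, with a median of 2466 UMIs per barcode. The sham data held 6337 barcodes and 11307405 UMIs, with a median of 1424. After filtering, 8287 MI cells and 5944 sham cells were kept. All intervals below are 95% intervals that cover counting error only, and all ratios are of MI over sham.

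Macrophage/monocyte-like cells made up a larger share of the MI library than of the sham library, and endothelial-like cells a far smaller one. Macrophage/monocyte-like cells were 46.2% (45.1 to 47.2) of MI cells and 24.2% (23.1 to 25.3) of sham cells, a log2 ratio of 0.93 (0.84 to 1.03). Endothelial-like cells were 5.80% (5.31 to 6.33) in MI and 36.5% (35.3 to 37.7) in sham, a log2 ratio of -2.65 (-2.83 to -2.48). Fibroblast-like cells took nearly the same share of both, 31.3% (30.3 to 32.3) in MI and 31.6% (30.4 to 32.8) in sham.

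Among the smaller classes, T/NK-like cells were 2.04% (1.75 to 2.37) of MI and 0.824% (0.610 to 1.09) of sham cells, and B cell-like cells numbered 124 of the MI and 32 of the sham cells. Mural-like cells, the pericytes and smooth muscle cells of the vessel wall, were 1.59% (1.33 to 1.89) and 3.23% (2.80 to 3.71). In sham, 140 of the 192 mural-like cells were in cluster 20, which also carried the endothelial marker Cdh5. Lymphatic endothelial-like cells were 0.398% (0.274 to 0.559) and 1.30% (1.02 to 1.62), and mesothelial-like cells of the epicardium 1.06% (0.853 to 1.31) and 1.41% (1.13 to 1.75). A further 10.2% (9.53 to 10.8) of MI cells and 0.454% (0.300 to 0.660) of sham cells stayed unnamed. Of these, cluster 6 carried fibroblast markers, but its 10 leading genes included the mesothelial markers Wt1 and Lrrn4. It held 7.75% of MI and 0.0168% of sham cells, and cluster 11, whose best marker class was macrophage/monocyte with 3 markers detected but whose 10 leading genes included the dendritic cell marker Cd209a, held 2.43% and 0.437%. With both given their best marker class, an assignment chosen after seeing the data, the log2 ratio of the fibroblast-like share was 0.30 instead of -0.01. With each library clustered on its own it was -0.82. In that setting 1454 MI cells were fibroblast-like and 1922 unnamed, against 2592 and 843 in the main one. The direction of the fibroblast-like share thus depends on the clustering and on which clusters are named. The mural-like ratio was -1.02 and turned to 1.21 at Leiden resolution 0.4. There 633 MI cells were mural-like and 2093 fibroblast-like, against 132 and 2592 in the main setting. The mesothelial-like ratio of -0.41 was 0.35 with each library clustered on its own. It was -5.80 (-9.16 to -3.62, 2 MI cells) at Leiden resolution 0.4, and -6.91 (-12.51 to -4.12, 1 MI cell) with doublets kept. Every barcode in both tables had at least 500 genes with a UMI, and median UMIs differed between the libraries in some classes (5191 in MI and 1486 in sham for fibroblast-like cells), so that cells of low RNA content can be missing from these shares.

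**Figure D1:**
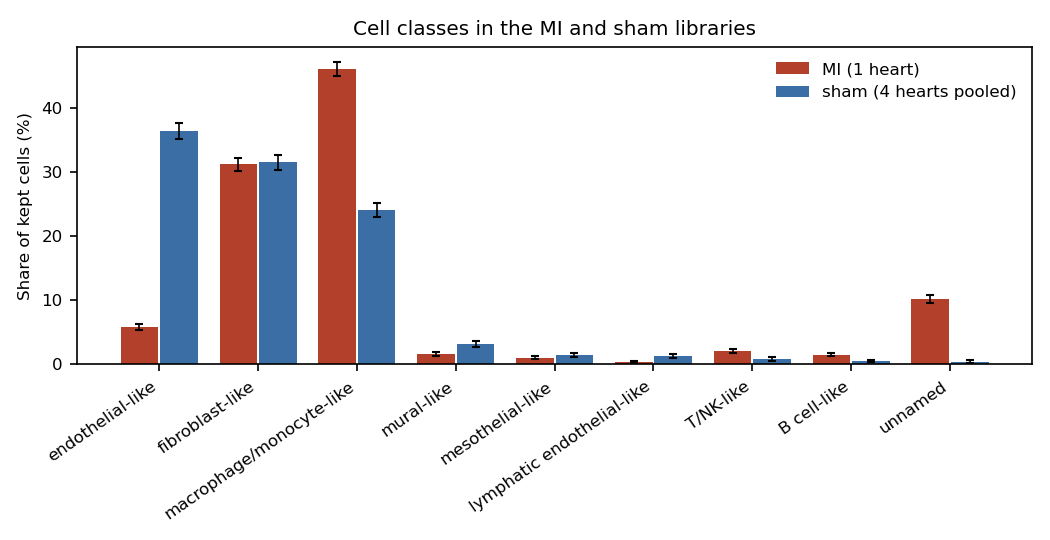
Bars give the share of kept cells (percent, vertical axis) of each class in the MI library (red, 1 heart) and the sham library (blue, 4 hearts pooled), with exact binomial 95% intervals that cover counting error only. Endothelial-like cells stood at 5.80% in MI and 36.5% in sham, and macrophage/monocyte-like cells at 46.2% and 24.2%.

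Fibroblast-like cells of the MI library carried more mRNA of the contractile, injury matrix and collagen lists, and less of the homeostatic fibroblast list. Cthrc1, which encodes a secreted protein of injured tissue, stood at 1107 CPM (1090.3 to 1123) in MI and 2.85 CPM (1.31 to 5.42) in sham, a log2 ratio of 8.60 (7.67 to 9.73). Acta2, smooth muscle alpha-actin, stood at 2326 CPM (2302 to 2349.7) in MI and 7.93 CPM (5.13 to 11.7) in sham, a log2 ratio of 8.20 (7.63 to 8.82). In the other direction Gsn, the actin-severing protein gelsolin, was at 299 CPM (290.3 to 307) in MI and 16202 CPM (16061 to 16343) in sham, a log2 ratio of -5.76 (-5.80 to -5.72). Dcn, the gene of the proteoglycan decorin, was at 1481 CPM (1462 to 1500) in MI and 15535 CPM (15397 to 15673) in sham, a log2 ratio of -3.39 (-3.41 to -3.37).

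The 12 higher genes whose intervals lay farthest from 0 included Cthrc1 and 4 genes of the contractile apparatus. Besides Acta2, these were Tagln at a log2 ratio of 7.96 (7.24 to 8.80), Cnn1 at a minimum of 6.48 and Actg2 at 6.95 (5.59 to 8.82). The fibrillar collagen chain Col11a1 stood at 7.64 (6.71 to 8.77), and P4ha3, a subunit of the enzyme that hydroxylates collagen prolines, at a minimum of 6.12. The matricellular gene Wisp1 was at a minimum of 7.68 and the imprinted noncoding RNA H19 at 6.08 (5.40 to 6.86). Ddah1, which degrades the nitric oxide synthase inhibitor dimethylarginine, was at 10.05 (7.57 to 15.35), Ddit4l at 7.50 (5.64 to 10.54) and Wfdc18 at a minimum of 5.85. Ratios written as a minimum or at least, or as a value or lower, have 0 UMIs in 1 library and were computed against a floor of 3 counts.

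Among the 12 lower genes chosen the same way were the carboxylesterase Ces1d at -9.84 or lower, the methyltransferase Inmt at -9.84 (-11.72 to -8.47) and the matrix protein tenascin X, Tnxb, at -9.07 (-10.13 to -8.18). Myoc stood at -9.07 (-12.12 to -7.20), the circadian-output transcription factor Hlf at -7.96 (-8.77 to -7.25) and the glutathione transferase Gsta3 at -7.80 (-8.38 to -7.28). The ferritin receptor Scara5 was at -7.35 (-7.85 to -6.88), Clec3b, which encodes tetranectin, at -7.08 (-7.33 to -6.84) and the opioid precursor Penk at -7.21 (-7.95 to -6.55). Icosl, Lsamp and the transporter Abca8a were at -7.66, -7.23 and -6.45.

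By list, all 10 measured homeostatic fibroblast genes were at least 2-fold lower, with a median log2 ratio of -3.41 (-3.48 to -3.35), below every one of 10000 random lists matched on expression; Pi16 was at -5.76. Of 12 injury-associated matrix genes 11 were at least 2-fold higher, with a median of 4.33 (4.14 to 4.51), and tenascin C, Tnc, was at 5.79 (5.07 to 6.63). Of 18 fibrillar collagen and collagen processing genes 10 were at least 2-fold higher and 0 lower, with a median of 1.73 (1.65 to 1.82); the crosslinking enzyme Lox was at 5.30 and Col1a1 at 3.57. These medians lay above all random lists, as did that of the contractile genes, 5.08 (4.82 to 5.47). The cell cycle list had a median of 3.70 (3.31 to 4.00), with 13 of 14 members at least 2-fold higher and the proliferation marker Mki67 at 4.20. Complement genes had a median of -2.84 (-2.91 to -2.73), with C3 at -4.24, immediate early genes -1.39 (-1.45 to -1.31), with Nr4a1 at -2.93, and basement membrane genes -1.07 (-1.29 to -0.95), with Lama2 at -3.02. Matrifibrocyte genes, a set described in mature scars, had a median of 2.65 (2.51 to 2.81) over 6 members, with Comp at 4.79, and secreted Wnt antagonists 2.21 (1.83 to 2.69) over 5.

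Lists on metalloproteinases and inhibitors, small leucine-rich proteoglycans and chemokines held members on both sides in fibroblast-like cells. Their medians were -0.74, -0.84 and -0.81; the inhibitor Timp1 was at 4.50 and the protease Adamts5 at -2.97, while Fmod was at 6.26 and Podn at -4.96, and Ccl9 at 4.09 against -7.08 for the eotaxin gene Ccl11. After thinning each cell to 500 UMIs, Acta2 was seen in 50.6% of MI and 0.479% of sham fibroblast-like cells (85.5% and 1.22% unthinned), and in 7.85% of MI lymphocytes, whose median was 1237 UMIs. Pi16 was seen in 1.62% and 32.9% after thinning (9.72% and 56.3% unthinned). The class was cluster 3 in sham and clusters 0, 8 and 15 in MI, the last 2 made of cycling cells, and with 1 library per group a cluster mostly of 1 library may be that library, not a type. The median over all genes was -0.25 in fibroblast-like and -0.12 in macrophage/monocyte-like cells, and median-of-ratios scaling moves log2 ratios by 0.30 and 0.14 there, by 0.14 in mural-like and by 0.11 in mesothelial-like cells.

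In the GRCm38 annotation Cthrc1 lies on chromosome 15, 39076932 to 39087121, Acta2 on chromosome 19, 34241090 to 34255590, and H19 on chromosome 7, 142575529 to 142578143. Spp1 lies on chromosome 5, 104435118 to 104441050, Lyve1 on chromosome 7, 110850607 to 110863239, Lrg1 on chromosome 17, 56119678 to 56122001 and Lpl on chromosome 8, 68880491 to 68907448. All but H19, a long noncoding RNA gene, are annotated as protein-coding.

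Macrophage/monocyte-like cells of the MI library carried more mRNA of the lipid-associated macrophage list and less of the tissue-resident and MHC class II lists. Spp1, which encodes the secreted phosphoprotein osteopontin, stood at 2203 CPM (2169.7 to 2237) in MI and 2.69 CPM (0.986 to 5.85) in sham, a log2 ratio of 9.68 (8.56 to 11.13). Lyve1, a hyaluronan receptor of resident macrophages, stood at 52.1 CPM (47.1 to 57.5) in MI and 1514 CPM (1464 to 1566) in sham, a log2 ratio of -4.86 (-5.02 to -4.71). Cd74, the invariant chain of MHC class II, stood at 988 CPM (966 to 1011) in MI and 6050.5 CPM (5949 to 6153) in sham, a log2 ratio of -2.61 (-2.65 to -2.57).

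Among the higher genes whose intervals lay farthest from 0, the glycoprotein Gpnmb was at 7.71 (6.16 to 9.99), arginase 1, Arg1, at 6.93 (5.71 to 8.55) and Syngr1 at 6.79 (5.24 to 9.07). Thbs1, thrombospondin 1, was at 6.21 (5.16 to 7.52), the acute phase gene Saa3 at 5.23 (4.42 to 6.18), the chitinase-like Chi3l3 at 6.25 (4.39 to 9.30) and the fatty acid binding protein Fabp5 at 4.75 (4.33 to 5.19). The collagen-related genes Col1a1, Col1a2, Lox and Cthrc1 were also among these 12, at log2 ratios of 5.66, 4.54, at least 5.43 and at least 4.74. Col1a2 stood at 1050.3 CPM in MI macrophage/monocyte-like cells and at 2311 CPM in MI lymphocytes, which should lack it (1443 CPM without the 3 of them that held most collagen UMIs), and it was seen in 40.4% and 52.9% of these cells after thinning, so it is read as background.

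The lower genes whose intervals lay farthest from 0 were Lyve1, Retnla, resistin-like alpha, at -9.13 (-9.87 to -8.49), the galactose-binding lectin Mgl2 at -7.97 (-8.65 to -7.37) and the phospholipase Pla2g2d at -7.71 (-10.00 to -6.14). The phosphatidylserine receptor Timd4 was at -5.19 (-5.89 to -4.56), Cmah at -5.49 (-6.07 to -4.96), Lilra5 at -5.28 (-5.82 to -4.78) and the sialyltransferase St3gal6 at -4.67 (-5.11 to -4.25). Bank1, Xlr, Chp2 and Leprel1 were at -4.69, -4.46, -4.51 and -4.95.

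Tissue-resident macrophage genes had a median log2 ratio of -3.12 (-3.18 to -3.05), with 9 of 10 at least 2-fold lower and Cbr2 at -3.99. MHC class II genes had a median of -1.18 (-1.24 to -1.14), with 6 of 7 at least 2-fold lower and H2-Ab1 at -1.18; their medians were at percentiles 0 and 0.0400 of the random lists. Lipid-associated genes had a median of 2.48 (2.31 to 2.67) and inflammatory monocyte genes 1.46 (1.21 to 1.56), with 8 of 11 and 6 of 11 at least 2-fold higher, and the monocyte chemokine receptor Ccr2 was at 1.46. Complement genes stood at -0.75 (-1.19 to -0.54), with C1qa at -1.70, and chemokines at -0.50 (-0.68 to -0.34), with Ccl6 at -1.52 and Ccl7 at -1.65. The interferon response list had a median of -0.11 (-0.24 to 0.10), with Ifi27l2a at -2.08 and Ifit2 at 1.40. Glycolysis and hypoxia genes had a median of 0.64 (0.50 to 0.73) and cell cycle genes 0.78 (0.60 to 0.92). After thinning, Spp1 was seen in 36.2% of MI macrophage/monocyte-like cells and in 5.46% of MI lymphocytes (55.2% and 12.6% unthinned), and Lyve1 in 1.86% of MI and 37.8% of sham macrophage/monocyte-like cells (3.45% and 54.5% unthinned). Cluster 4 held most of the class in sham and clusters 1, 5 and 7 in MI, with median UMIs of 1695 in MI and 1374 in sham. Retnla, Chi3l3, Xlr and Lilra5 have close relatives in the genome, so their counts are uncertain where reads could be shared.

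Endothelial-like cells of the MI library carried less mRNA of the capillary list and more of the activation list. Cd36, the fatty acid translocase, stood at 305 CPM (282 to 328) in MI and 4211 CPM (4147 to 4275) in sham, a log2 ratio of -3.79 (-3.90 to -3.68). Lipoprotein lipase, Lpl, was at 62.3 CPM (52.4 to 73.5) in MI and 1273 CPM (1238 to 1309) in sham, a log2 ratio of -4.35 (-4.61 to -4.11). Plvap, the diaphragm protein of fenestrae and caveolae, stood at 916 CPM (877 to 956) in MI and 56.6 CPM (49.4 to 64.5) in sham, a log2 ratio of 4.02 (3.82 to 4.22). Lrg1, which encodes a secreted glycoprotein, was at 315 CPM (292 to 339) in MI and 6.60 CPM (4.31 to 9.67) in sham, a log2 ratio of 5.58 (5.02 to 6.20).

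Among the higher genes whose intervals lay farthest from 0, Thbs1 was at 6.60 (5.82 to 7.52), N-cadherin, Cdh2, at 6.78 (5.64 to 8.23), the TGF-beta-induced matrix protein Tgfbi at 5.84 (5.32 to 6.42) and fibronectin, Fn1, at 5.33 (5.09 to 5.58). Gdf6, a growth factor of the bone morphogenetic protein family, was at 6.36 (4.98 to 8.25), Clca1 at 5.97 (4.98 to 7.20), Col23a1 at 5.60 (4.96 to 6.32) and Tmem158 at 5.33 (4.89 to 5.80). Sprr1a was at a minimum of 5.98 and P4ha3 at a minimum of 5.18. Col3a1 was at 5.27 (5.01 to 5.54), with 1203 CPM in MI endothelial-like cells beside 999 CPM in MI lymphocytes (638 CPM without the same 3 cells). It was seen in 31.4% and 33.1% of these cells after thinning. Of its 2705 UMIs in MI endothelial-like cells, 237 were left without clusters 13 and 16. Most of its signal thus lay in these clusters, and the class average cannot tell whether it is background.

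The lower genes whose intervals lay farthest from 0 were, besides Lpl, the chloride channel Clic5 at -5.50 (-5.95 to -5.08), the nucleoside transporter Slc28a2 at -6.17 (-7.62 to -5.04) and the glycerol channel Aqp7 at -6.58 (-8.86 to -5.02). The protease inhibitor Timp4 was at -5.70 (-6.51 to -5.00), carbonic anhydrase Car4 at -5.25 (-6.13 to -4.50) and the retinoic acid hydroxylase Cyp26b1 at -5.18 or lower. Tppp3, Cyp4b1, Prg4, the interferon-inducible chemokine Cxcl9 and Nepn were at -5.71, -4.89, -4.91, -5.15 and -5.72.

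All 10 capillary genes were at least 2-fold lower, with a median of -2.99 (-3.23 to -2.82), below every random list, while 8 of 9 activation genes were at least 2-fold higher, with a median of 3.62 (3.17 to 4.11), above every random list. The interferon response list stood at -2.57 (-2.95 to -2.16), with 10 of 11 members at least 2-fold lower and the antiviral Rsad2 at -4.34. TGF-beta response genes had a median of 1.03 (0.69 to 1.49), with Ctgf at 3.37, basement membrane genes 0.57 (0.49 to 0.64), with Col18a1 at 4.48, and angiogenic tip-cell genes 0.61 (0.42 to 0.69), with Esm1 at 2.85 and Aplnr at -1.15. Chemokines stood at 0.96 (0.66 to 1.30), but at -0.84 with each library clustered on its own. Immediate early genes had a median of -1.05 (-1.13 to -0.85), with Egr1 at -1.53. The fatty acid uptake and oxidation list as a whole had a median of 0.02 (-0.49 to 0.11), with 4 of 11 at least 2-fold lower. After thinning, Plvap was seen in 35.1% of MI and 2.77% of sham endothelial-like cells (78.0% and 4.98% unthinned) and in 1.71% of MI lymphocytes. Cd36 was seen in 13.1% and 79.8% (34.7% and 92.7% unthinned), with 9.88% in sham lymphocytes. Cluster 2 held most of the class in sham and clusters 10 and 13 in MI, and median UMIs were 3364 in MI and 1274 in sham.

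The endothelial-like class had a different makeup in each library. Cluster 13 held 215 of the 481 MI cells of the class and 2 of its 2169 sham cells, and cluster 16 held 11 and 172; both had the natriuretic peptide receptor Npr3 and Igf2 among their 10 leading genes. Without both clusters, a comparison chosen after seeing the data, the capillary median was -2.37 and the activation median 4.00, with Cd36 at -2.73 (-2.84 to -2.61), Lpl at -3.45 (-3.72 to -3.19), Plvap at 6.72 (6.10 to 7.40) and Lrg1 at 6.80 (6.17 to 7.50). Cdh2 was then at 2.93 (1.40 to 4.63) and Tmem158 at 2.87 (1.85 to 3.96), while Gdf6, Col23a1 and P4ha3 were left with 0, 1 and 1 UMIs in MI and 1, 2 and 0 in sham cells. Aplnr, a member of the tip-cell list, was at -0.04 (-0.26 to 0.18), an interval that includes 0, and Esm1 at 3.97 (3.32 to 4.68). Col3a1 was at 3.16 (2.82 to 3.51), Col18a1 at 5.63 (5.19 to 6.10), Fn1 at 4.58 (4.24 to 4.94), Tgfbi at 4.86 (4.06 to 5.78) and Rsad2 at -3.24 (-3.62 to -2.88). Among the lower genes Aqp7 was at -5.45 (-7.73 to -3.90) and Car4 at -4.12 (-5.00 to -3.37), and the 12 with the intervals farthest from 0 lay between -5.45 and -3.45. The medians of the TGF-beta response, tip-cell, immediate early and fatty acid lists were then 1.80, 1.48, -0.33 and -0.62, and those of chemokines and sarcomere genes turned to -0.16 and -2.03.

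**Figure D2:**
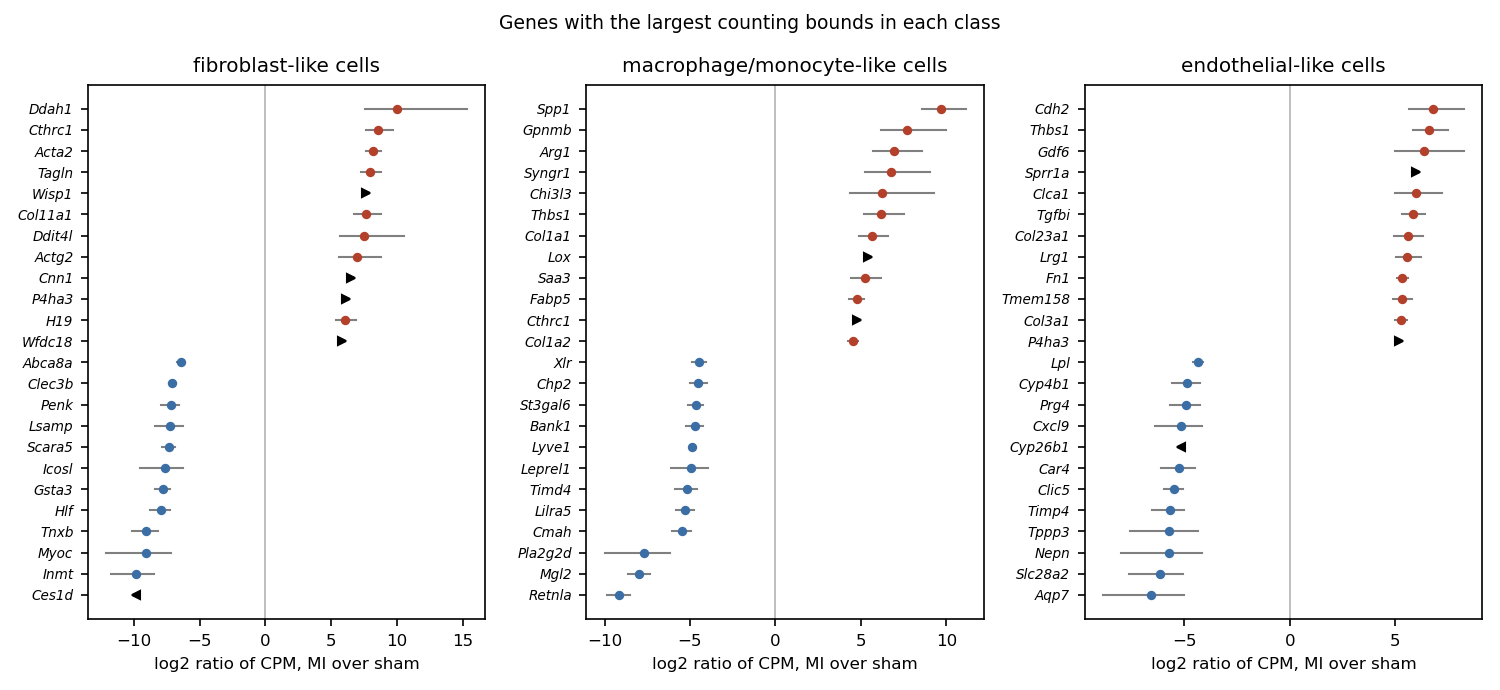
Each point is the log2 ratio of CPM (horizontal axis) of a gene between the MI and sham libraries in fibroblast-like, macrophage/monocyte-like and endothelial-like cells, red above 0 and blue below, with lines for the 95% counting interval and black triangles for genes with 0 UMIs in 1 library, drawn at the bound against 3 counts. Cthrc1 at 8.60 in fibroblast-like, Spp1 at 9.68 in macrophage/monocyte-like and Lpl at -4.35 in endothelial-like cells are examples.

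In mural-like cells of the MI library, the contractile and collagen lists were higher. The median of the contractile list was 1.47 (1.35 to 1.61) and that of the collagen list 2.71 (2.48 to 3.39). Ankrd1 was at a minimum of 6.61, Timp1 at 7.58 (5.09 to 12.89) and S100a6 at 4.73 (4.44 to 5.03). The class was mainly cluster 17 in MI and cluster 20 in sham. Acta2 stood at 5531 CPM in cluster 17 and 838 CPM in cluster 20, while the smooth muscle marker Myh11 stood at 556 and 952 CPM. The list medians of the class can therefore reflect a different mix of pericytes and smooth muscle cells in each library. Cluster 20 also carried the endothelial adhesion gene Cdh5 at 621 CPM, beside 8.92 CPM in cluster 17 and 1028 CPM in the endothelial-like cluster 2. Cdh5 was seen in 75.0% of the cells of cluster 20 and in 3.89% of those of cluster 17. The lower values of Cd36 (-6.08), Clic5 (-7.79) and Kdr (-6.20) in the class stand beside that endothelial signal in the sham cells. The sham side of the contractile and collagen medians rests mostly on the same cells.

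Mesothelial-like cells, which form the outer layer of the heart, showed higher Lgals1, the carbohydrate-binding galectin 1, at 4.76 (4.45 to 5.09), Fn1 at 3.83 (3.05 to 4.75) and Timp1 at 3.63 (2.87 to 4.51) in MI. The antioxidant enzyme Gpx3 was lower, at 127 CPM (101 to 158) in MI and 3659.9 CPM (3401 to 3934) in sham, a log2 ratio of -4.85 (-5.20 to -4.52), as were the natriuretic peptide receptor Npr3 at -6.67 (-8.56 to -5.28) and the water channel Aqp1 at -4.79 (-5.38 to -4.25). Collagen genes had a median of 1.78 (1.57 to 2.10). The class held 88 MI and 84 sham cells.

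Across the 5 classes compared, the median log2 ratio of 11 mitochondrially encoded mRNAs lay below 0, at -0.66 in fibroblast-like, -0.95 in macrophage/monocyte-like, -0.68 in endothelial-like, -0.88 in mural-like and -0.77 in mesothelial-like cells. All mitochondrial transcripts together, which include the ribosomal RNA mt-Rnr2, took 6.57% in MI and 5.63% in sham of the UMIs of all kept cells. They took 5.89% in MI and 4.96% in sham in fibroblast-like, 8.59% in MI and 5.87% in sham in macrophage/monocyte-like, 6.81% in MI and 5.94% in sham in endothelial-like, 6.38% in MI and 6.35% in sham in mural-like and 5.69% in MI and 6.15% in sham in mesothelial-like cells, with mt-Rnr2 alone at 5.43% of MI and 3.57% of sham UMIs. Nuclear genes of the respiratory chain had medians of 0.55, 0.36, 0.59, 0.35 and 0.31 in the same 5 classes. Heat shock genes had medians of -0.25, -0.61 and -0.27 in the first 3 of these classes, the first turning to 0.05 under median-of-ratios scaling. Sarcomere transcripts of cardiomyocytes had medians of -3.55, -4.07 and 1.62 in the same 3 classes, the last at -0.11 with each library clustered on its own, and no cluster was named cardiomyocyte-like.

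**Figure D3:**
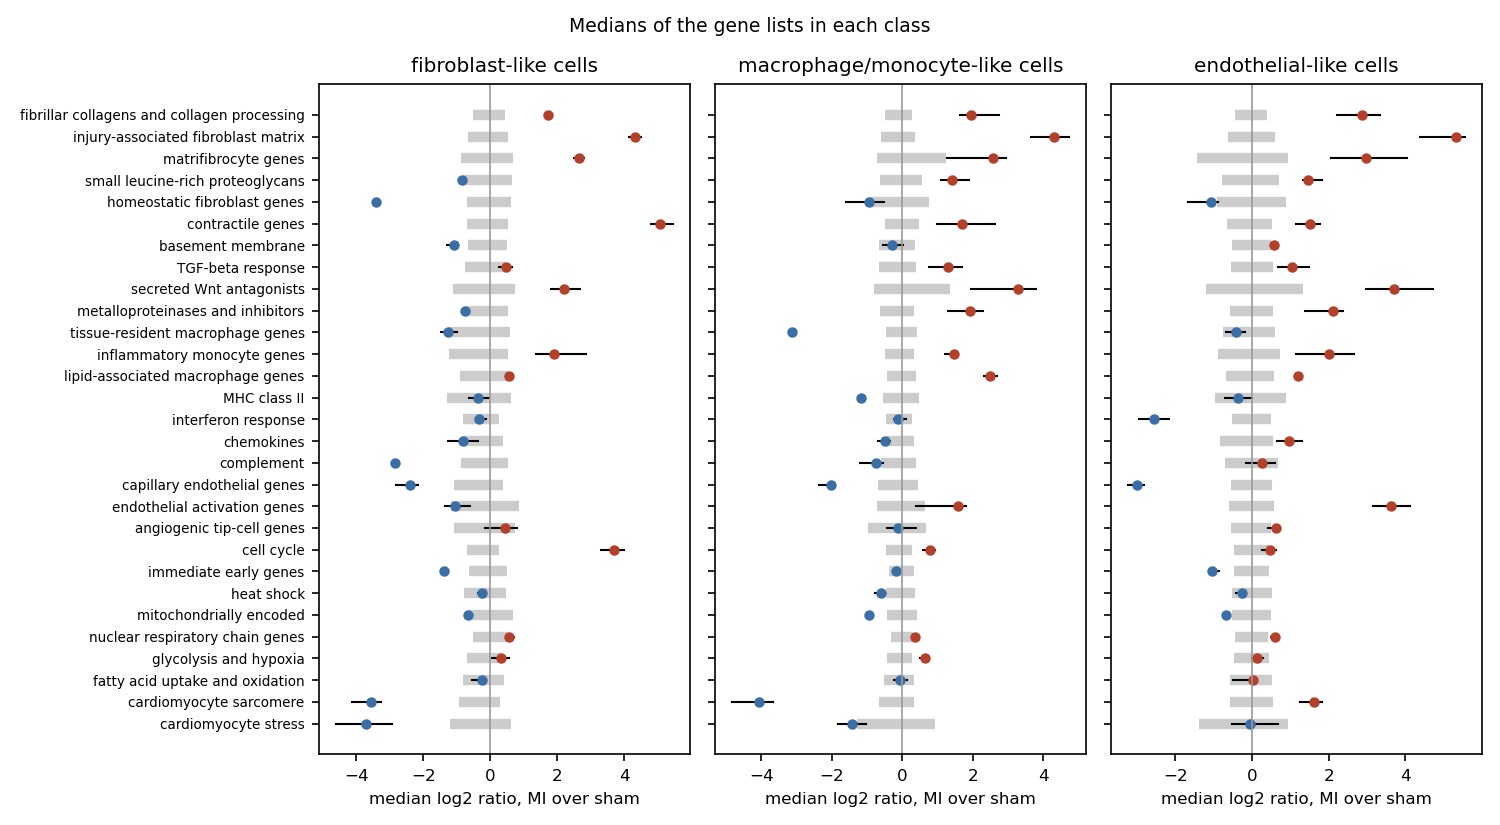
Each point is the median log2 ratio (horizontal axis) of a gene list between the MI and sham libraries in 3 classes, red above 0 and blue below, with a black line for its 95% counting interval and a grey bar for the middle 95% of 10000 random lists matched on expression. The homeostatic fibroblast list lies at -3.41 in fibroblast-like cells and the capillary list at -2.99 in endothelial-like cells.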

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

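The tests of depth in macrophage clusters, of cycling cells, of fibroblast doublets among lymphocytes, of dilution by macrophages and of cells near the gene minimum were chosen only after the results they bear on were seen. Values from here on are log2 ratios of MI over sham unless another unit is named. Gene lists stood out when their median lay outside the middle 95% of random lists in opposite directions in different classes, with counting intervals that excluded 0. The differences between classes were not tested. In simulated data 3.75%, 7.50% and 4.75% of 400 unchanged lists lay outside that range in fibroblast-like, macrophage/monocyte-like and endothelial-like cells. These rates are for single classes, and how often an unchanged list would meet the whole rule was not simulated. Small leucine-rich proteoglycans had medians of 1.42 in macrophage/monocyte-like, 1.47 in endothelial-like and -0.84 in fibroblast-like cells. After thinning, Bgn, Aspn and Ogn were seen in 3.92%, 2.51% and 2.88% of MI macrophage/monocyte-like cells. The shares in MI lymphocytes were higher, at 7.85%, 3.75% and 6.83%, so the higher median in macrophage/monocyte-like cells may be background. Metalloproteinases and inhibitors stood at 1.91, 2.10 and -0.74 in the same order. The basement membrane list was at 0.57 in endothelial-like cells, percentile 98.8, and at -1.07 in fibroblast-like cells. Chemokines were at 0.96 in endothelial-like, -0.81 in fibroblast-like and -0.50 in macrophage/monocyte-like cells, percentile 1.32, and cardiomyocyte sarcomere genes at 1.62, -3.55 and -4.07. With each library clustered on its own, the endothelial-like chemokine and sarcomere medians were -0.84 and -0.11. Without clusters 13 and 16, also chosen after seeing the data, the endothelial-like medians were 0.20 for proteoglycans, 0.93 for metalloproteinases and inhibitors, 0.75 for basement membrane, -0.16 for chemokines and -2.03 for sarcomere genes.

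Signals outside the compared classes were unnamed clusters and a gene listed in 1 table. Cluster 6 held 7.75% of MI cells, with Saa3 at 539 CPM, Clu at 1456 CPM and Wt1 at 181 CPM beside the fibroblast marker Dcn at 4510 CPM. In the mesothelial-like cluster 18 Saa3, Clu and Wt1 stood at 131, 1458 and 305 CPM, and in the fibroblast-like cluster 0 at 11.2, 40.9 and 3.86 CPM. Cluster 11 held 2.43% of MI cells, with H2-Ab1 at 13010 CPM and Cd209a at 319 CPM. Of the dendritic cell markers, Cd209a and Flt3 were seen in 24.7% and 22.9% of its cells, but Ccr7 and Zbtb46 in 3.08% and 2.20%. The macrophage markers C1qa and Csf1r were seen in 6.17% and 6.61%. Ighg2b, an immunoglobulin heavy chain gene, had 667 UMIs in the MI table and was not listed in the sham table.

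Median UMIs per fibroblast-like cell were 3.49 times as high in MI as in sham. Without the cycling clusters the ratio was 3.30, and among the 75% of cells with the lowest doublet scores 3.64, which argues against both as the whole cause. Deeper sequencing of the whole MI library would raise macrophages alike, but the ratio was 0.943 (0.817 to 1.29, from drawing cells with replacement) in the cycling cluster 7 and 1.24 (1.04 to 1.42) in cluster 9, macrophage/monocyte-like clusters that both libraries held with at most 12% of cells under 600 genes, which argues against it as the whole cause. The ratio was 3.19 in mesothelial-like, 3.21 in mural-like, 2.64 in endothelial-like and 1.59 in lymphatic endothelial-like cells. The mesothelial-like class was cluster 18 in both libraries, so higher UMIs were not limited to fibroblast-like cells. The mural-like and endothelial-like values compare different main clusters of each library. Within the mural-like cluster 17 the ratio was 6.33 (5.09 to 6.94). Within the endothelial-like cluster 2 it was 1.13 (0.986 to 2.22), with 21 MI and 1899 sham cells, 23.9% of the latter under 600 genes. The ratio was 0.978 in T/NK-like and 0.958 in B cell-like cells. Of the T/NK-like cells, 31.4% and 30.6% had under 600 genes in MI and sham, so the minimum may hide a gap there. A smaller depth gap and more RNA per fibroblast after injury stay open, and neither was tested further.

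Collagen UMIs appeared in 270 of 293 MI lymphocytes, with a median of 3 per cell, while doublets with fibroblasts as the whole source would leave most cells at 0. A part may come from doublets or misplaced fibroblasts, since 3 cells held 39.6% of these UMIs, against 5.19% expected from depth. Over 10 abundant fibroblast genes, the lymphocyte level stood at a nearly fixed share of the library's level, with the highest share 1.34 times the lowest, or 1.46 times without those 3 cells, which is consistent with RNA from fibroblasts, free or in doublets. For Col1a2 the share was 8.65% without them and 6.30% in macrophage/monocyte-like cells, where Fn1 was at 17.1%, so free RNA alone leaves Fn1 there open. The higher matrix lists of macrophage/monocyte-like, endothelial-like, mural-like and mesothelial-like cells may in part come from the same source.

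The lower endothelial-like share in MI was weighed against macrophage influx and against the gene minimum. Macrophages would dilute fibroblasts and endothelial cells alike, but the log2 ratio of endothelial-like cells per fibroblast-like cell was -2.64. Under the alternatives for filters and clustering it lay between -2.96 and -1.83, the latter with each library clustered on its own. More fibroblasts would lower this ratio too, and the cell cycle list was higher in MI fibroblast-like cells (median 3.70). Dilution by a growing fibroblast-like class therefore stays open. Shallow MI cells lost below the minimum would leave many cells just above it, but 3.33% of MI and 21.9% of sham endothelial-like cells had under 600 genes, a ratio of 0.152. This compares mainly clusters 10 and 13 in MI with cluster 2 in sham, so it cannot decide whether shallow MI cells of cluster 2 were lost. Within cluster 2, 9.52% of 21 MI and 23.9% of 1899 sham cells had under 600 genes. Unequal release of endothelial cells from scar and healthy tissue, the pooling of 4 hearts against 1, and a loss of capillaries after infarction stay open and were not tested.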

How the results depend on the processing

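Both free RNA subtractions, thinning before summing, leaving out cycling clusters or endothelial clusters 13 and 16, and the best marker class for unnamed clusters were tests chosen only after the results were seen. No paired analysis was possible because each group had 1 library. The 7 main list medians kept their sign in every alternative with a value. Of their values, 27, 21 and 32 in fibroblast-like, macrophage/monocyte-like and endothelial-like cells stayed within the counting interval and 21, 11 and 2 moved outside it. Ratios of the genes named in the text, most chosen as far from 0, kept their sign wherever given; 147, 46, 68, 10 and 3 of their values moved outside the interval in these 3 classes and in mural-like and mesothelial-like cells. The endothelial-like share stayed within its interval. The 500-gene minimum removed no cell and is not counted, and the free-RNA profile from barcodes under 100 genes was not run, with 0 such barcodes. The first free RNA level drew 39.6% in MI and 76.6% in sham of its collagen UMIs from 3 cells. Both levels exceed the 6.21% and 2.72% that collagens reached in macrophage/monocyte-like cells, so fibroblast genes were removed there by construction and their sign tests nothing. Col1a1, Col1a2, Cthrc1 and Lox had no ratio after either in these cells, Gdf6, Col23a1 and P4ha3 none without clusters 13 and 16, and mesothelial-like genes none at Leiden resolution 0.4 or with doublets kept, with under 50 MI cells. Changed signs are given only if the main value's interval excluded 0. Except for the free RNA effect and median-of-ratios scaling, which shifts every gene of a class alike, the cause was not tested.

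With no limit on the mitochondrial share, moved values were the fibroblast-like share at -0.68 and in fibroblast-like cells collagens at 1.62 and homeostatic genes at -3.15. At Leiden resolution 0.4, moved values were the fibroblast-like share at -0.32 and the mesothelial-like share at -5.80 and in fibroblast-like cells homeostatic genes at -3.23. The mural-like share at 1.21 changed sign. At Leiden resolution 1.5, moved values were the fibroblast-like share at -0.66 and in fibroblast-like cells collagens at 1.62 and homeostatic genes at -3.15. With each library clustered on its own, moved values were the fibroblast-like share at -0.82, the mesothelial-like share at 0.35 and the unnamed share a bound of at least 8.84, in fibroblast-like cells collagens at 1.56 and homeostatic genes at -3.18 and in macrophage/monocyte-like cells MHC class II at -1.27. In fibroblast-like cells interferon genes at 0.0659 changed sign. In endothelial-like cells chemokines at -0.84, cell cycle genes at -0.0142 and sarcomere genes at -0.11 changed sign. With unnamed clusters given their best marker class, moved values were the fibroblast-like share at 0.30, in fibroblast-like cells injury matrix at 4.04 and in macrophage/monocyte-like cells MHC class II at -0.91. In fibroblast-like cells MHC class II at 0.24 changed sign. With at most 10% mitochondrial UMIs, moved values were the macrophage/monocyte-like share at 0.75 and in macrophage/monocyte-like cells resident macrophage genes at -3.21 and MHC class II at -1.10. In fibroblast-like cells cardiomyocyte stress genes at 1.14 changed sign. With doublets kept, moved values were the mesothelial-like share at -6.91 and the unnamed share at 2.52 and in fibroblast-like cells collagens at 1.82. Under median-of-ratios scaling, moved values were in fibroblast-like cells collagens at 2.03, injury matrix at 4.63 and homeostatic genes at -3.11 and in macrophage/monocyte-like cells resident macrophage genes at -2.98 and MHC class II at -1.04. In fibroblast-like cells heat shock genes at 0.0486 and fatty acid genes at 0.0524 changed sign. Under CPM without the 50 most abundant genes, moved values were in fibroblast-like cells collagens at 1.82 and homeostatic genes at -3.33 and in macrophage/monocyte-like cells MHC class II at -1.14. With each cell thinned to 500 UMIs, moved values were in fibroblast-like cells collagens at 1.83 and homeostatic genes at -3.27 and in macrophage/monocyte-like cells resident macrophage genes at -3.04. In fibroblast-like cells MHC class II at 0.0369 changed sign. With members of 1 UMI in each library, moved values were in fibroblast-like cells collagens at 1.65. Under the mean over cells of counts per 10000, moved values were in fibroblast-like cells injury matrix at 4.52 and homeostatic genes at -3.20, in macrophage/monocyte-like cells resident macrophage genes at -2.98 and MHC class II at -1.14 and in endothelial-like cells capillary genes at -2.72. In fibroblast-like cells MHC class II at 0.0906 changed sign. Without cycling clusters, moved values were in fibroblast-like cells homeostatic genes at -3.22 and in macrophage/monocyte-like cells MHC class II at -1.13. With free RNA subtracted, moved values were in fibroblast-like cells homeostatic genes at -3.51. In fibroblast-like cells inflammatory monocyte genes at -0.57, lipid-associated macrophage genes at -0.96 and capillary genes at 2.504 changed sign. In macrophage/monocyte-like cells collagens at -1.90, contractile genes at -3.80, capillary genes at 1.53 and activation genes at -0.14 changed sign. In endothelial-like cells homeostatic genes at 1.42, resident macrophage genes at 2.19 and inflammatory monocyte genes at -0.16 changed sign. At the second free RNA level, in macrophage/monocyte-like cells collagens at -0.94 and contractile genes at -1.84 changed sign. In endothelial-like cells homeostatic genes at 0.90 and resident macrophage genes at 1.22 changed sign. Without endothelial clusters 13 and 16, moved values were in endothelial-like cells capillary genes at -2.37. In endothelial-like cells chemokines at -0.16, cell cycle genes at -0.91 and sarcomere genes at -2.03 changed sign.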

Other observations

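TGF-beta response genes had a median log2 ratio of 0.46 (0.27 to 0.64) in fibroblast-like cells, with 3 of 11 members at least 2-fold higher and 1 lower. In macrophage/monocyte-like cells the median of this list was 1.30 (0.76 to 1.71). Glycolysis and hypoxia genes stood at 0.32 (0.06 to 0.55) in fibroblast-like and 0.13 (-0.01 to 0.29) in endothelial-like cells. Immediate early genes in macrophage/monocyte-like cells stood at -0.19 (-0.27 to -0.10), and in endothelial-like cells the complement list was at 0.26 (-0.15 to 0.60), an interval that includes 0, and at -0.11 without clusters 13 and 16.

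The test of imprinted genes was fixed before its own values were seen, but after H19 had been seen among the higher genes of MI fibroblast-like cells. H19 is an imprinted gene, and a hypothesis was that other imprinted genes were higher with it. The median log2 ratio of 12 such genes was 0.15, at percentile 88.1 of random lists, which leaves the hypothesis undecided. Mest was at 2.36 and Plagl1 at 2.29, while Ndn was at -1.27, Sgce at -1.37 and Igf2 at 0.02.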
